A study of Mus musculus with 4 samples.

How the data were processed

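RNA was profiled from the autopod, the distal part of the mouse limb bud that forms the hand or foot, of C57BL/6 embryos at embryonic day 11.25. Per the labels' protocols, embryos were dissected in cold buffer and kept in RNAlater, the part of the limb bud that matches the Hoxd13 expression domain was cut out, and total RNA was purified on columns and cleared of DNA. Fore- and hindlimb pieces both entered, per the series' design text, so the values are averages over both limbs. Biotin-labelled cRNA was made with a one-cycle Affymetrix protocol and hybridised to 4 arrays, 1 per sample. The 2 Hox13dKO samples came from embryos homozygous for a Hoxa13 null allele and for a deletion spanning Hoxd11, Hoxd12 and Hoxd13, and the 2 controls from wild-type embryos. Titles call the samples of a group biological replicates; how many embryos went into each is not given in the sources used here.

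The values analysed were the intensity per probe set that the authors deposited, on a linear scale. Per the submitters' processing notes they were made with MAS5, whose version is not given in the sources used here. MAS5 subtracts background, combines the perfect-match and mismatch probes of a probe set and scales the array. The deposited values bear a common scaling: the 2% trimmed mean was 500.003 on each of the 4 arrays. MAS5 detection calls were not used here, and cell-level scanner data were not analysed here, so background cannot be set per probe set and the arrays could not be summarised again by another method. The number of arrays, 2 per group, limits the precision, and no read depth exists for this assay.

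Of 45101 probe sets, 34958 carried 1 gene symbol in the platform annotation, 932 several and 9211 none. Among those with 1 symbol, 34754 were found by their gene ID in the RefSeq gene table of assembly GRCm38.p6 and 204 were not, and 0 symbols needed an update. That table served for names and for the order of neighbouring genes, and no coordinates are given. The 64 Affymetrix control probe sets were left out of the tests. Signals below the 20th percentile of all values, 14.1 signal units, were raised to it, and log2 was taken with no further normalization. Probe sets whose mean log2 signal over the 4 arrays reached the 40th percentile, a geometric mean of at least 39.6 units, were tested, which left 27022. Where every array of a group lay at the floor, the fold is given as a lower bound.

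Hox13dKO and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 6.05. Values are given as mean signal ± SD over 2 arrays per group and as log2 difference, Hox13dKO minus wild type, ± SE. For a gene with several probe sets the brightest by mean log2 signal among those with 1 symbol was used, which gave 13072 genes, and the direction of the others was checked. Genes named in the text are the 12 highest and 12 lowest log2 differences among genes past the threshold whose arrays separated fully by group, the targeted genes, the members of each gene list with the lowest p (up to 4), and all members of a list that are given as a count of 5 or fewer. Further genes past the threshold, and the list members Hoxa9, Hoxa10, Hoxd10, Sox9, Pax3, Adm, Ddit4, Ndrg1 and Slc2a1, are named in the text after their values were seen. The 30 gene lists cover the Hox clusters, limb axes, signalling pathways, skeletal and connective tissue, limb identity, other cell types, proliferation, cell death, stress, hypoxia, housekeeping and sex. They, the test, the rule for names and the alternative settings were set before the data were examined. Some genes sit in several lists. Lists with at least 3 measured genes (29 of the 30) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. With an estimated correlation camera has only 2 residual degrees of freedom. A list can thus fail it for lack of power as well as for correlated genes. Hindlimb identity had 2 measured members and is given as values. Figures were drawn with matplotlib 3.10.9.

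The alternatives were quantile normalization, median centring, no floor, a pseudocount in place of the floor, no filter, a stricter filter at the 60th percentile, eBayes without trend, robust eBayes, the replicate number as a block, 1 probe set per gene, leaving out cross-hybridising probe sets, leaving out each array, an adjusted p of 0.10, an added 1.5-fold limit and a 2-fold rule over all pairings of arrays. For lists they also included the estimated correlation, fry and the mean over a gene's probe sets. The steps were tested on simulated arrays, 2 against 2, with the spread of these data. Over 10 runs with 200 changed probe sets among 27022, 9.3% of changes of 2-fold and 47.7% of 4-fold were recovered, with 4.4 false calls per run and 0 of wrong sign. In 50 runs camera found a set of 15 genes shifted by 0.5 on the log2 scale in 100% and called an unshifted set in 4%. The simulated genes varied independently of each other, while the hypoxia and glycolysis list had an estimated correlation of 0.707. These rates therefore do not carry over to lists of correlated genes.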

Results

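Expression was measured in the autopod at E11.25 in 2 Hox13dKO and 2 wild-type samples. The comparison asks which transcripts differ in the distal limb bud that lacks the Hox genes of its terminal domain. Hox13dKO embryos are homozygous for a Hoxa13 null allele and for a deletion of Hoxd11 to Hoxd13, genes that pattern the digits and wrist in a dose-dependent way. Each array was scaled by the authors to the same trimmed mean, 500.003 signal units, and median signals were 66.1 and 81.2 in Hox13dKO and 65.8 and 85.7 in wild type. Across probe sets, log2 signals correlated with r = 0.962 between the Hox13dKO arrays and r = 0.958 between the wild-type arrays, and r ranged from 0.951 to 0.962 between groups. Ratios of 5' to 3' actin signal were 0.728 and 0.771 in Hox13dKO, 0.473 in wild type replicate 1 and 0.764 in wild type replicate 2. Poly-A spike-in controls read higher in Hox13dKO, with geometric means of 925 and 810 against 678 and 529.

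The targeted genes had far lower signals in Hox13dKO, with both arrays below both wild-type arrays for all 5 of their probe sets. Hoxd13, which specifies digits, read 7.69 ± 2.68 in Hox13dKO and 15328 ± 1114 in wild type (SD, n = 2 each). Both Hox13dKO arrays lay below the floor, so Hoxd13 was at least 1085-fold lower (adjusted p = 6.41e-07), and by its other probe set, also at the floor on both, at least 264-fold lower (adjusted p = 0.000310). Hoxd12 read 19.4 ± 20.02 against 1690 ± 681, a log2 difference of -6.22 ± 0.48 (SE; adjusted p = 0.00423), with 1 Hox13dKO array at the floor; it was -5.59 without Hox13dKO replicate 1 and -6.84 without Hox13dKO replicate 2. Hoxa13, the HoxA gene of the autopod, read 55.2 ± 3.99 against 1153 ± 439, 20.1-fold lower by the fitted log2 difference (adjusted p = 0.00423). Hoxd11 kept a signal of 401 ± 74.6 against 1788 ± 60.9, 4.50-fold lower by the fitted log2 difference (adjusted p = 0.00778). Where the probes of these genes lie relative to the removed sequence is not known here. The remaining signals of Hoxd11, Hoxa13 and, on 1 array, Hoxd12 thus cannot be assigned to transcript or to background. Any background in them would make the true folds larger than those fitted.

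**Figure D1:**
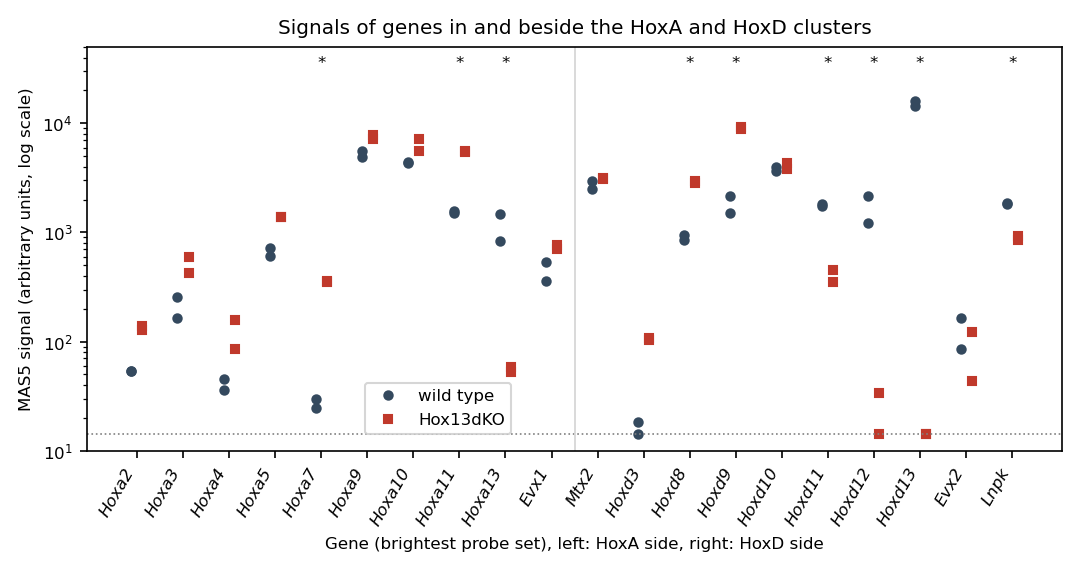
MAS5 signal on a log axis for genes in and beside the HoxA (left) and HoxD (right) clusters, with each array as a point (circles, wild type; squares, Hox13dKO) and values below the floor of 14.1 drawn at the dotted line. Stars mark genes past an adjusted p of 0.05; Hoxa13 and Hoxd11 to Hoxd13 lie lower in Hox13dKO, and Hoxa7, Hoxa11, Hoxd8 and Hoxd9 lie higher.

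Apart from the targeted genes, the autopod of Hox13dKO embryos had more transcript of Hoxa7, Hoxa11, Hoxd8, Hoxd9, Shox2 and several collagen genes, and less of Gja3, Tmem30b, Sulf1 and Jag1. The highest log2 differences were those of Actc1, an actin of heart and embryonic skeletal muscle (3.76 ± 0.41 SE, 13.6-fold), and Hoxa7, a Hox gene of the trunk (3.72 ± 0.42). Actc1 read 1566 ± 970 in Hox13dKO against 105 ± 16.7 in wild type; it differed by 4.44 without Hox13dKO replicate 1, and by 3.08 and not past the threshold (adjusted p = 0.119) without Hox13dKO replicate 2. Hoxa7 read 355 ± 4.30 against 27.0 ± 3.52. Its wild-type signals lay above the floor but are dim and not shown to be above background. The size of its log2 difference and its rank rest on those signals. Actc1 and Hoxa7 were followed by Cyp1b1, a cytochrome P450 (2.37 ± 0.22), Hoxd9 (2.33 ± 0.18, 5.03-fold) and Hoxa11 (1.86 ± 0.13, 3.63-fold). Both Hoxd9 and Hoxa11 pattern the arm and forearm. Tshz2, a teashirt-family zinc finger gene, differed by 1.74 ± 0.22, Col25a1, a membrane-bound collagen, by 1.72 ± 0.23, and Shox2, needed for the upper arm and thigh, by 1.71 ± 0.23. Bnip3, a mitochondrial protein induced in hypoxia (1.69 ± 0.23), Hoxd8 (1.68 ± 0.14), the ubiquitin ligase gene Pdzrn3 (1.62 ± 0.17) and the collagen VI gene Col6a3 (1.51 ± 0.20) completed the 12 highest.

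Among lower transcripts beyond the targeted genes, Gja3, a connexin of gap junctions, read 104 ± 44.7 in Hox13dKO against 1108 ± 73.5 in wild type (SD, n = 2 each), 11.22-fold lower. Tmem30b, a subunit of lipid flippases, was 8.39-fold lower (5.37-fold without Hox13dKO replicate 1, 13.1-fold without Hox13dKO replicate 2), and Sulf1, an extracellular sulfatase that edits heparan sulfate and so modulates growth factor signalling, 5.67-fold lower. Clstn2, a calsyntenin (-2.36 ± 0.33 SE), Dpysl3, a cytoskeletal protein of growing neurites (-2.10 ± 0.22), Thsd4, a matrix protein with thrombospondin repeats (-2.06 ± 0.22), Cdc42ep3, an effector of the GTPase Cdc42 (-2.05 ± 0.16), and Ltbp1, which binds latent TGF-beta (-1.90 ± 0.20), were the other five of the 12 lowest. Jag1, a Notch ligand, was 3.66-fold lower, the kinase gene Sgk1 3.70-fold lower, and Tfap2b, an AP-2 transcription factor gene, 2.83-fold lower. By other probe sets Tfap2b differed by -0.64 and Dpysl3 by -0.99 and -2.14. In those at -0.64 and -0.99 the arrays of the groups overlapped. Adjusted p ranged from 0.00423 to 0.0478 over the 20 untargeted genes among the 12 highest and 12 lowest.

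In all, 56 of 27022 probe sets passed an adjusted p of 0.05 in limma, 31 higher and 25 lower in Hox13dKO, and they named 44 genes (25 higher, 19 lower). All 56 had both Hox13dKO arrays on the same side of both wild-type arrays. Chance gives that separation to 33.3% of unselected probe sets. The 56 were selected for a large difference on these same arrays, so their separation is no independent support. Of all probe sets tested, 1692 (6.26%) had an unadjusted p under 0.05, a share not far above the cutoff itself. A split of the replicate 1 arrays from the replicate 2 arrays had more, 2561. By brightest probe set 40 genes passed. Aff3, an elongation-complex gene (0.99 ± 0.14), was the exception among these 40 in that another of its probe sets differed in the opposite direction, by -0.01. The count was sensitive to the fit: without the filter on dim probe sets it was 0 (3159 at an unadjusted p under 0.05), and without the intensity trend it was 1, a Hoxd13 probe set. With 1 probe set per gene it was 95. It was 20 without Hox13dKO replicate 1, 11 without Hox13dKO replicate 2, 306 without wild type replicate 1 and 525 without wild type replicate 2. Of the 24 genes with the highest and lowest differences, 11 passed without Hox13dKO replicate 1 and 8 without Hox13dKO replicate 2, the latter being Hoxd13, Hoxd12, Hoxa13, Hoxd11, Hoxa11, Gja3, Tmem30b and Sulf1. Aff3, Col3a1 and Socs2 did not pass after median centring, and Aff3, Bnip3 and Clstn2 did not pass with no floor. In the fits with an array left out, the lone array of a group is assumed to vary like the arrays of the other group.

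**Figure D2:**
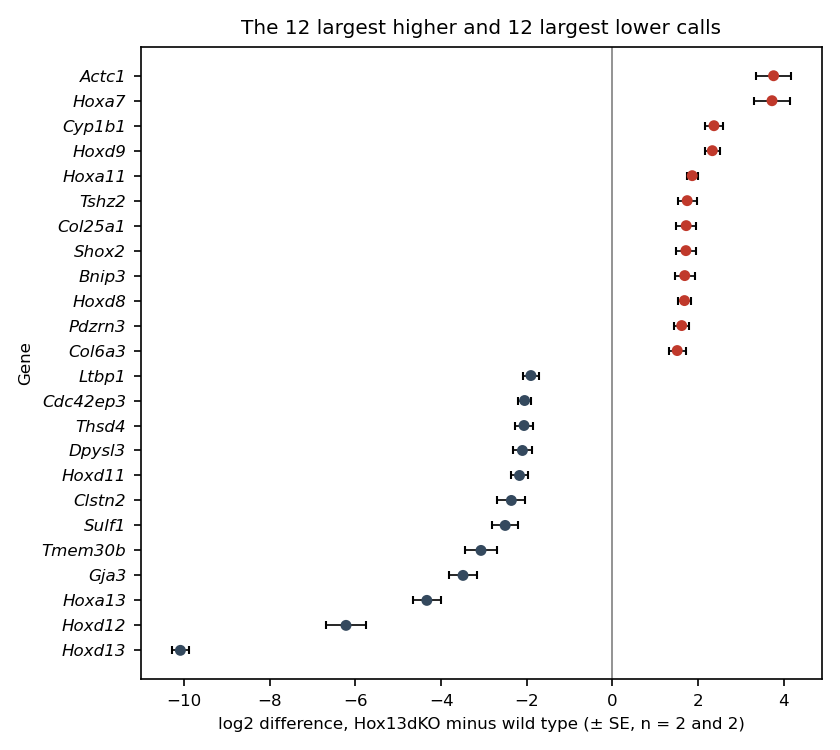
Log2 difference, Hox13dKO minus wild type, of the 12 highest and 12 lowest genes past an adjusted p of 0.05 (points), with SE bars over 2 arrays per group. Actc1 and Hoxa7 lie near 4 and Hoxd13, whose Hox13dKO arrays are at the floor, lies at -10.08.

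Genes of the HoxA and HoxD clusters and their borders other than the targeted ones rose as a group. Of 17 measured, Hoxa7, Hoxa11, Hoxd8 and Hoxd9 were higher and Lnpk, an endoplasmic reticulum gene beside HoxD, was lower (-1.05 ± 0.15 SE, 2.07-fold lower); adjusted over the list alone, 12 were higher and 1 was lower. The list's median log2 difference was 1.06 (camera adjusted p = 1.64e-11; adjusted p = 0.354 with an estimated correlation). Hoxd10, between Hoxd9 and the deleted Hoxd11, differed by 0.08 ± 0.14, and Hoxa9 and Hoxa10 by 0.52 each, none of them past the threshold. Lnpk no longer passed after quantile normalization or median centring. The 4 targeted genes fell as a list (median -5.28, adjusted p = 1.64e-11; adjusted p = 0.354 with an estimated correlation). HoxB and HoxC genes had a median of 0.18 (0.11 without Hox13dKO replicate 2, 0.096 without wild type replicate 1 and 0.29 without wild type replicate 2) with 0 of 11 past the threshold and 1 higher adjusted over the list alone, Hoxc4 (at least 3.06, with both wild-type arrays at the floor), beside Hoxc5 (1.28 ± 0.46), Hoxc6 (0.91 ± 0.38) and Hoxb9 (1.13 ± 0.55). Their list passed narrowly (adjusted p = 0.0426; adjusted p = 0.354 with an estimated correlation) and did not pass with no floor (adjusted p = 0.282), a pseudocount (0.283), no filter (0.160), a stricter filter (0.213), without cross-hybridising probe sets (0.0821), with the mean over probe sets (0.0645), by fry (0.0573), without Hox13dKO replicate 1 (0.147) or without wild type replicate 1 (0.166).

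Markers of the proximal limb were higher as a list at the preset correlation. Of 13 measured, 3 were higher (Hoxa11, Hoxd9 and Shox2) and 7 adjusted over the list alone, 11 had positive differences, and the median was 0.82 (adjusted p = 4.17e-06; adjusted p = 0.354 with an estimated correlation). Tbx18, a T-box gene of proximal mesenchyme, differed by 0.995 ± 0.20 (SE), and another of its probe sets passed (1.39 ± 0.19). Without the 3 Hox genes, a choice made after seeing the data, the median of the other 10 was 0.64. Forelimb identity genes (Tbx5, 1.02 ± 0.32, with Hoxc4 and Hoxc5) passed as a list of 3 with 0 members past the threshold and 3 higher adjusted over the list alone (median 1.28, adjusted p = 2.18e-05; adjusted p = 0.354 with an estimated correlation). Hoxc4 and Hoxc5 are also members of the HoxB and HoxC list. The forelimb list was not tested with no floor or a pseudocount, which left out Hoxc4 and kept 2 members, or with the stricter filter, which left out Hoxc4 and Hoxc5 and kept 1. The measured hindlimb identity genes were Tbx4, at 0.31 ± 0.24, and Hoxc10, at -0.17 ± 0.33. Each sample pooled fore- and hindlimb pieces, in proportions not stated.

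Along the anterior-posterior axis, anterior markers rose as a list and posterior markers did not pass. Of 8 anterior markers 0 passed alone and 3 were higher adjusted over the list alone (median 0.59, adjusted p = 0.000414; adjusted p = 0.354 with an estimated correlation). They were led by Pax9, a paired-box gene of the anterior margin (1.83 ± 0.31 SE), Asb4 (0.67 ± 0.17), Irx3 (0.97 ± 0.30) and Gli3, the main repressor of Hedgehog targets in the limb (0.52 ± 0.19). Of 8 posterior markers 0 passed, and adjusted over the list alone 1 was higher and 3 were lower (adjusted p = 0.223). Shh, the posterior signal itself, differed by -1.32 ± 0.42, Bmp2 by -1.05 ± 0.18, Tbx2 by -1.29 ± 0.39 and Tbx3 by 0.83 ± 0.26. The Hedgehog pathway list had 0 of 14 past, with 2 higher and 2 lower adjusted over the list alone (adjusted p = 0.692). Its target Gli1 differed by -0.90 ± 0.22 and its coreceptor genes Boc and Gas1 by 0.96 ± 0.19 and 0.57 ± 0.14. Other Gas1 probe sets differed by 0.57 and, at dim signals and in the opposite direction, by -0.83.

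Genes that the literature names as HOX13 targets differed in both directions. Of 22 measured, Jag1 (-1.87 ± 0.17 SE) and Tfap2b (-1.50 ± 0.19) were lower and 0 were higher. Other Jag1 probe sets passed as well (-2.25 and -1.96), while another of Tfap2b did not (-0.64). Adjusted over the list alone, 5 were lower and 5 higher. The list did not pass as a shift to either side (adjusted p = 0.761). Bmpr1b, a BMP receptor of digit condensations, differed by -1.36 ± 0.22, Aldh1a2, the main retinoic acid synthase of the embryo, by -1.08 ± 0.19, and Sostdc1, a secreted BMP and Wnt antagonist, by 1.71 ± 0.29. The others counted over the list alone were Bmp2, lower, and Sall3 (1.26 ± 0.22), Epha3 (0.93 ± 0.21), Gdf5 (1.15 ± 0.32) and Meis2 (0.82 ± 0.26), higher. Another Sall3 probe set differed in the opposite direction, by -0.39. Other Meis2 probe sets differed by 1.49, 0.86 and -0.02. In the BMP pathway list 0 of 21 passed and the list did not shift (adjusted p = 0.581), with 5 higher and 3 lower adjusted over the list alone. The higher were Sostdc1, Bmp4 (0.73 ± 0.18), Gdf5, Id2 (0.52 ± 0.16) and Id4 (0.78 ± 0.26), and the lower Bmpr1b, Bmp2 and Bmper, a secreted BMP binder (-1.31 ± 0.32).

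Skeletal and connective tissue genes rose as lists. Cartilage condensation genes had 0 of 24 past the threshold, with 3 higher and 1 lower adjusted over the list alone, and a median of 0.22 (adjusted p = 0.0162; adjusted p = 0.354 with an estimated correlation). Col2a1, the main collagen of cartilage, differed by 0.61 ± 0.14 (SE), Cdh2, a cadherin of condensing mesenchyme, by 0.52 ± 0.14, and Gdf5, which marks future joints, by 1.15 ± 0.32, while Bmpr1b was the lower member. Sox9, the master regulator of chondrocytes, differed by 0.03 ± 0.20. This call was lost with a stricter filter (0.0648), without Hox13dKO replicate 1 (0.109) and without wild type replicate 1 (0.0845, median 0.09). Tendon and connective tissue genes had 1 of 12 past, Col3a1 (0.96 ± 0.13), and 4 higher adjusted over the list alone, with Col1a1 at 1.16 ± 0.18, Lum at 1.02 ± 0.26 and Osr2 at 0.68 ± 0.22 (median 0.37, adjusted p = 0.000816; adjusted p = 0.354 with an estimated correlation). Their median was 0.79 without Hox13dKO replicate 1 and 0.15 without Hox13dKO replicate 2.

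Among signalling lists, the apical ridge markers, genes of the ectodermal ridge that drives outgrowth, passed with 0 of 15 members past the threshold and 3 higher adjusted over the list alone. Fgf4 differed by 1.79 ± 0.43 (SE), Bmp4 by 0.73 ± 0.18, Fgf8 by 0.83 ± 0.22 and Sp6 by -0.66 ± 0.22. Other Sp6 probe sets differed by -0.44 and 0.74. The list median was 0.25 (camera adjusted p = 0.0182 at the preset correlation and 0.354 with an estimated correlation). The call was lost without Hox13dKO replicate 2 (adjusted p = 0.0676) and without wild type replicate 1 (0.0918), and the median was 0.61 without wild type replicate 2. FGF response genes had 0 of 15 past and 0 adjusted over the list alone (adjusted p = 0.699), with Fgfr1 at 0.47 ± 0.16 and Dusp6 at 0.38 ± 0.14. Other Fgfr1 probe sets differed by 0.25 and -0.08. Wnt pathway genes had 0 of 27 past, and 1 adjusted over the list alone, Ror1, a receptor for Wnt5a (1.74 ± 0.31; adjusted p of the list = 0.205). In the retinoic acid list 1 of 13 passed, Crabp1, a cytoplasmic retinoic acid binding protein (1.18 ± 0.17, 2.27-fold higher), while 1 was lower adjusted over the list alone, Aldh1a2 (adjusted p of the list = 0.393). Crabp1 did not pass after median centring or with no floor. Eph, ephrin and adhesion genes had 0 of 30 past, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0703). They were Epha3 (0.93 ± 0.21), Pcdh19 (1.08 ± 0.27), Efna5 (0.72 ± 0.18) and Cdh2 (0.52 ± 0.14), and, lower, Efna1 (-0.82 ± 0.20). The list passed without cross-hybridising probe sets (adjusted p = 0.0449), with the mean over probe sets (0.00389), without Hox13dKO replicate 2 (0.0157) and without wild type replicate 1 (0.0398).

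Markers of other cell types that a limb bud holds were also compared. Muscle progenitor markers had 1 of 10 past, Actc1, and 3 higher adjusted over the list alone (median 0.87, adjusted p = 0.000626; adjusted p = 0.397 with an estimated correlation). The myogenic factor genes Myog, Myod1 and Myf5 differed by 3.54 ± 0.67, 1.93 ± 0.59 and 1.25 ± 0.46 (SE), and Pax3, which marks migrating precursors, by -1.16 ± 0.88. With a stricter filter, which removed dim members, the muscle median was -0.25 (adjusted p = 0.713), and without Hox13dKO replicate 2 it was 0.56. Endothelial markers had 0 of 18 past and 1 higher adjusted over the list alone, Sox18 (0.88 ± 0.18), a factor of vessel growth (median 0.20, adjusted p = 0.0148; adjusted p = 0.354 with an estimated correlation); the call was lost without Hox13dKO replicate 2 (0.0852) and without wild type replicate 1 (0.0918, median 0.11), and the median was 0.40 without wild type replicate 2. Erythroid markers had 0 of 12 past and 3 higher adjusted over the list alone (median 0.59, adjusted p = 0.0024; adjusted p = 0.397 with an estimated correlation), with Car2 at 0.997 ± 0.26, the heme synthesis gene Alas2 at 1.13 ± 0.32 and the anion exchanger gene Slc4a1 at 0.87 ± 0.26. Their call was lost without wild type replicate 1 (adjusted p = 0.251, median 0.31). Macrophage and leukocyte markers had 0 of 15 past and 1 higher adjusted over the list alone, the mannose receptor gene Mrc1 (1.30 ± 0.24), beside the complement gene C1qa (2.02 ± 0.79); their median was 0.41 (adjusted p = 0.000303; adjusted p = 0.354 with an estimated correlation), and 0.27 without wild type replicate 1. Ectoderm markers did not shift (0 of 17 past and 0 adjusted over the list alone, adjusted p = 0.761), with Krt8 at -0.61 ± 0.21 and Krt5 at 0.53 ± 0.24. Nerve and Schwann cell markers had 0 of 6 past and 2 lower adjusted over the list alone, the neuronal genes Stmn2 (-1.08 ± 0.26) and Tubb3 (-1.29 ± 0.37; adjusted p of the list = 0.110), and the list passed without Hox13dKO replicate 2 (0.00115, median -1.04), while without Hox13dKO replicate 1 its median turned to 0.21 (adjusted p = 0.956).

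Hypoxia and glycolysis genes were higher as a list at the preset correlation. All 20 measured had positive differences; by brightest probe set 1 passed, Bnip3, and 15 were higher adjusted over the list alone (median 0.91, adjusted p = 5.63e-13; adjusted p = 0.354 with an estimated correlation). P4ha1, a collagen prolyl hydroxylase, differed by 1.16 ± 0.18 (SE), and the glycolytic enzyme genes Aldoa and Tpi1 by 0.83 ± 0.13 and 0.74 ± 0.13. Aldoa and the kinase gene Pdk1 (0.87 ± 0.18) did not pass by their brightest probe sets, but 2 other Aldoa probe sets (0.95 and 0.94) and 1 of Pdk1 (1.37) did. The Hox13dKO arrays differed from each other in several members, and the median was 1.37 without Hox13dKO replicate 1 and 0.65 without Hox13dKO replicate 2. Without the 4 members in which these arrays differed most (Ndrg1, Adm, Ddit4 and Slc2a1), a choice made after seeing the data, the median of the other 16 was 0.85. Hox13dKO replicate 2 also had a signal of 7798 for the heat shock gene Hspa1b, against 285 in Hox13dKO replicate 1 and 205 and 185 in wild type. Immediate early and stress genes as a list had 0 of 19 past and 0 adjusted over the list alone (adjusted p = 0.201), led by Ier3 (1.42 ± 0.34) and Egr3 (-1.41 ± 0.51), but the list passed without Hox13dKO replicate 1 (0.00244) and with a stricter filter (0.0349), while without Hox13dKO replicate 2 its median turned from 0.25 to -0.095 (adjusted p = 0.694).

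Cell cycle genes were slightly lower as a list, with 0 of 28 past the threshold, 0 adjusted over the list alone and 24 below 0 (median -0.11, adjusted p = 0.0457; adjusted p = 0.354 with an estimated correlation). Rrm2 and Plk1 differed by -0.37 ± 0.13 and -0.38 ± 0.14 (SE), and the inhibitor gene Cdkn1c by 0.45 ± 0.17. This call was lost without any 1 of the 4 arrays (adjusted p = 0.144 and 0.167 without Hox13dKO replicate 1 and replicate 2, 0.230 and 0.104 without wild type replicate 1 and replicate 2), with a pseudocount (0.0505) and with the mean over probe sets (0.0597). Targets of p53 and cell death genes had 0 of 15 past and 0 adjusted over the list alone (adjusted p = 0.761), with Pmaip1 at 0.77 ± 0.24. Housekeeping genes had 0 of 14 past and 1 higher adjusted over the list alone, Pgk1, also a glycolytic gene (0.64 ± 0.13; adjusted p of the list = 0.0802). Sex-linked genes had 0 of 4 past and 1 higher adjusted over the list alone, Xist (1.01 ± 0.27; adjusted p of the list = 0.0934); the list passed without Hox13dKO replicate 1 (0.0228), without wild type replicate 1 (0.00551), without cross-hybridising probe sets (0.0367) and with the mean over probe sets (0.0146). Without wild type replicate 2 its median turned from 0.35 to -0.12 (adjusted p = 0.961).

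**Figure D3:**
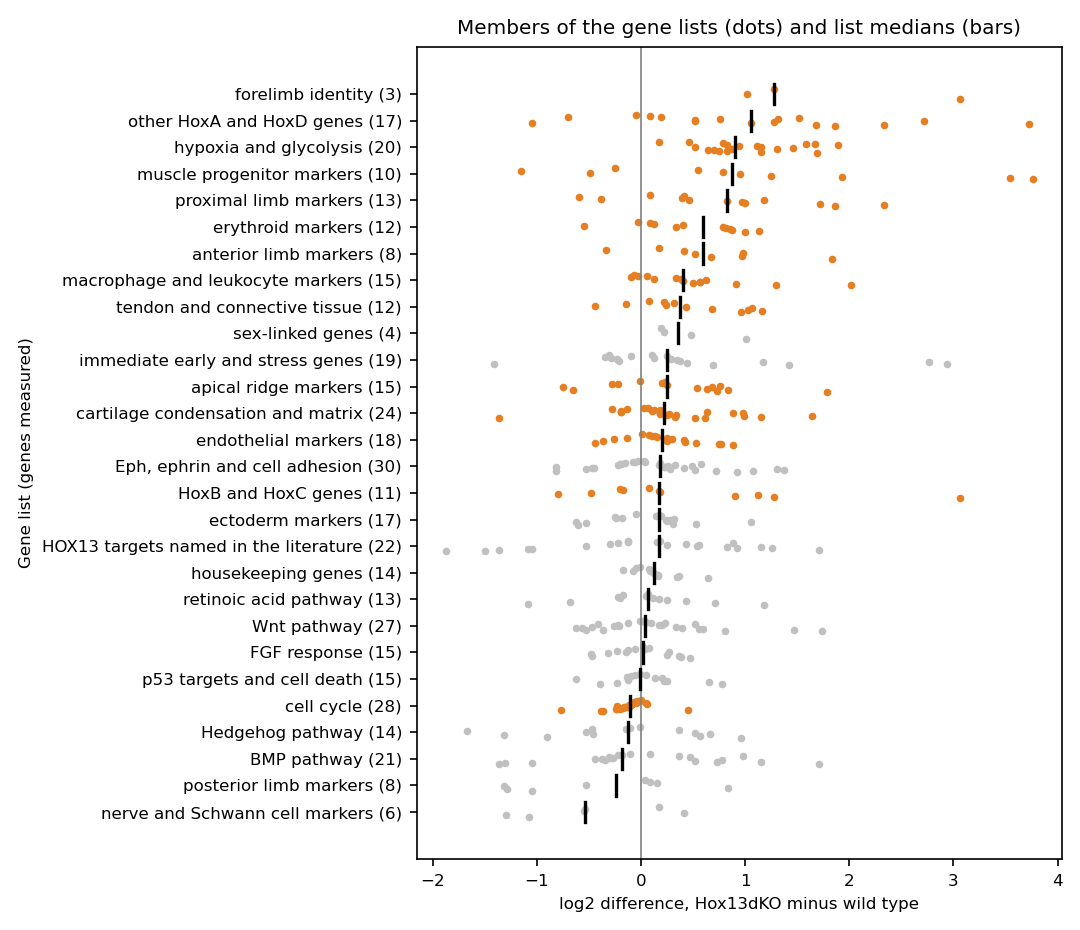
Log2 difference, Hox13dKO minus wild type, of each measured gene (points) in 28 of the gene lists, with list medians as bars and the number of genes measured in brackets; the targeted genes and hindlimb identity are not drawn. Orange lists passed an adjusted p of 0.05 at the preset correlation, and 0 lists did with an estimated correlation; hypoxia and glycolysis genes all lie above 0.

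Over the 29 lists tested, 15 passed with camera at the preset correlation, 13 higher and 2 lower. The lower lists were the cell cycle and the targeted genes. The fall of the targeted genes is a check of the genotype, a deletion of Hoxd11 to Hoxd13 and a Hoxa13 null allele, and not a separate result. None of these 15 list calls held with a correlation estimated from the data (0 of 29). That camera test has 2 residual degrees of freedom, and the targeted genes did not pass it either (adjusted p = 0.354). The estimated correlation was -0.138 for anterior markers, below the preset 0.01, and 0.707 for hypoxia and glycolysis genes. Failing that test therefore does not by itself show that correlated genes made a call. By fry, which asks if a list moves on balance to either side, 6 lists passed. Processing settings that moved the median of a passing list by over 1.5 times without ending its call were the stricter filter (other HoxA and HoxD genes 0.64, anterior markers 0.97, apical ridge 0.40), the mean over probe sets (proximal markers 0.49, cartilage 0.35, apical ridge 0.54) and leaving out cross-hybridising probe sets (apical ridge 0.40). The 6 lists that passed by fry were the targeted genes, the other HoxA and HoxD genes, proximal markers, anterior markers, forelimb identity and the cell cycle.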

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

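Some control signals followed the groups and others did not. The poly-A spike-in controls, bacterial transcripts added to the RNA before labelling, lay higher in Hox13dKO for 24 of 24 probe sets, with a mean log2 difference of 0.53 ± 0.13 (SD over probe sets). Their geometric means were 925 and 810 on the Hox13dKO arrays and 678 and 529 on the wild-type arrays. Hybridisation controls, added after labelling, were 2246 and 2646 in Hox13dKO and 2083 and 2558 in wild type, higher on the replicate 2 array of each group and not split by genotype.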

How the results depend on the processing

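All 56 probe sets past the threshold kept their direction in each setting in which they were tested, but how many passed varied. Their arrays separated fully by group, so leaving out an array could not turn the direction. Changes to the filter or to eBayes leave the log2 difference as it is. From 56 (31 higher, 25 lower) the count went to 0 without the filter (limma; 3159 at an unadjusted p under 0.05), 1 (0 higher, 1 lower) with eBayes without trend, 95 (57 higher, 38 lower) with 1 probe set per gene, 111 at an adjusted p of 0.10 and 308 (173 higher, 135 lower) by the 2-fold rule over all pairings. With each array left out in turn it ranged from 11 to 525 (higher from 1 to 432, lower from 9 to 93). In the fit without the filter the prior degrees of freedom were 0.977 and without the trend 2, against 6.05. The targeted probe sets past the threshold were 5, but 0 without the filter and 1 without the trend; the 24 named genes were 0 and 1 in those settings and 8 to 24 with an array left out. The cause was not tested. The labels do not say that equal replicate numbers share a litter or a day, and their deviations from the group means correlated with 0.198; with 2 pairs the replicate block gave 418 probe sets (290 higher, 128 lower). It also ended the call of the HoxB and HoxC list (adjusted p = 0.0905). Of the lists 15 passed, 0 with an estimated correlation and 6 by fry.

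List medians that changed sign: FGF response, -0.013 after median centring and -0.024 with the stricter filter, -0.10 to 0.18 with arrays left out; p53 targets, 0.022 with no floor, 0.022 with a pseudocount, 0.050 with no filter and 0.049 with the mean over probe sets, -0.016 to 0.097 with arrays left out; posterior markers, 0.042 with no filter; muscle markers, -0.25 with the stricter filter, which leaves out members; and ectoderm markers, -0.085 with the mean over probe sets and -0.072 to 0.30 with arrays left out. With arrays left out, nerve markers ranged from -1.04 to 0.21, immediate early and stress genes from -0.095 to 0.34 and sex-linked genes from -0.12 to 0.83. Single genes that changed sign with arrays left out, none past the threshold, were Hoxd10 (-0.01 to 0.18), Evx2 (-1.46 to 0.048), Sox9 (-0.21 to 0.26), Eif2s3y (-0.10 to 0.54), Hspa1a (-0.43 to 5.95), Actb (-0.14 to 0.86), Kdm5d (-0.14 to 1.10) and Uty (-0.17 to 0.55). Low signals limit Hoxd13 and Hoxd12, whose Hox13dKO values lie at or near the floor.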

Other observations

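The tests on collagen genes, insulin-like growth factor genes, proximal tissue, hypoxia genes and other splits of the arrays were chosen after the results were seen; the test on genes beside the Hox clusters was chosen before its result. Several collagen genes were higher in Hox13dKO. Of 34 measured, Col25a1, Col6a3, Col1a2 (1.09 ± 0.14 SE, 2.12-fold) and Col3a1 passed the threshold higher and 0 lower, 26 had positive differences, and the median was 0.36. Since the genes past the threshold prompted the question, the hypothesis that collagen genes rise as a class was tested on the other 30, whose median was 0.28 (camera p = 2.17e-05; p = 0.0576 with an estimated correlation). Among these, Col8a2 differed by 1.90 ± 0.44, Col12a1 by 1.27 ± 0.50, Col1a1 by 1.16 ± 0.18 and Col6a1 by 1.11 ± 0.23, and at the other end Col5a3 by -0.92 ± 0.50. Genes of the insulin-like growth factor system, a driver of embryonic growth, all had positive differences, 11 of 11. Socs2, a feedback inhibitor of growth hormone signalling, passed (1.03 ± 0.14), Igf1, the ligand, differed by 2.25 ± 0.36 and passed by another probe set (2.82 ± 0.36), and Igfbp3 and Igfbp2, which bind the ligand, by 1.26 ± 0.19 and 1.16 ± 0.18. The family was put together after Socs2 and Igf1 had been seen, so the hypothesis of a rise as a class was tested on the other 9, whose median was 0.37 (camera p = 9.06e-05; p = 0.114 with an estimated correlation). These 9 still hold Igfbp3 and Igfbp2, and the 30 collagen genes still hold Col1a1. All were measured on the same arrays as the genes that prompted the questions. Neither class test is therefore independent support for a rise as a class.

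Other genes past the threshold that the lists do not hold were the chemokine gene Cxcl12 (1.44 ± 0.18 SE), Mab21l1 (1.27 ± 0.16), Cdo1, an enzyme of cysteine breakdown (1.23 ± 0.17), and Cbln1, a secreted cerebellin (1.16 ± 0.14), all higher. The protease gene Ctsc (-1.35 ± 0.15), Lmo2, a transcriptional cofactor gene (-1.31 ± 0.16), and Dipk2a (-1.55 ± 0.15) were lower.

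Proximal limb markers were higher in Hox13dKO as a list at the preset correlation (camera adjusted p = 4.17e-06) but not with an estimated correlation (0.354). After quantile normalization the list lay 0.85 above the median of all genes, with an SE of 0.24 for the mean of its members. A scaling factor common to an array moves the list and all genes alike, so it cannot give this gap. A candidate explanation is that the Hox13dKO pieces held more proximal tissue: the markers other than Hox genes were higher too (limma's camera gave a p of 0.000301 at the preset correlation and 0.0636 with an estimated correlation), and so were muscle markers (adjusted p = 0.000626; adjusted p = 0.397 with an estimated correlation). The muscle median turned to -0.25 with the stricter filter, so this support is limited. A shift of the distal cells themselves toward a proximal expression state, through loss of the targeted genes, is a biological alternative. It was not tested apart from a larger share of proximal tissue. Both remain open.

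Hypoxia and glycolysis genes were higher in Hox13dKO. Stress in Hox13dKO replicate 2 alone would leave Hox13dKO replicate 1 near wild type. Without Hox13dKO replicate 2 the list median was 0.65 (adjusted p = 3.00e-08 at the preset correlation). Of the 20 members, 17 were higher on Hox13dKO replicate 1 than on both wild-type arrays. The higher values were thus not confined to Hox13dKO replicate 2. That adjusted p presumes a correlation of 0.01, while 0.707 was estimated for the list, and it rests on Hox13dKO replicate 1 alone. It cannot tell a group difference from variation between arrays, so stress in Hox13dKO replicate 2 alone is not excluded. With all arrays and an estimated correlation the list did not pass (adjusted p = 0.354). After quantile normalization the list lay 0.93 above the median of all genes (SE 0.11), a gap that a scaling factor common to an array cannot give. Longer handling of the Hox13dKO pieces may have acted on both arrays: the immediate early and stress genes gave a camera p of 0.139 (adjusted p = 0.201; median -0.095 without Hox13dKO replicate 2), which does not decide it, and handling cannot be told apart from genotype because no time of dissection is given in the sources used here. A response to the loss of the targeted genes remains open and was not tested.

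Genes beside the targeted clusters could differ because DNA flanking the modified alleles came with them from another strain. Among the 25 nearest tested genes on each side of HoxA and HoxD, 9 of 100 had an unadjusted p under 0.05, against 914 of 12879 other genes (7.10%). The odds ratio was 1.29 (95% interval 0.572 to 2.58; Fisher's exact test, two-sided, p = 0.433). The interval reaches above a doubling, so flanking DNA cannot be told apart from no effect with so few neighbours.

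The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The genotype split gave 56 probe sets past the threshold, 1 of the 3 splits with as many, and the highest of the others gave 0. The split of replicate 1 arrays from replicate 2 arrays had 2561 probe sets at an unadjusted p under 0.05, against 1692 for genotype and 258 for the remaining split, and 287 at 2-fold in all pairings, against 308 and 79. That points to a structure of the samples or of the arrays that follows the replicate number. Hybridisation controls and median signals were also higher on both replicate 2 arrays, so the 2 kinds of structure cannot be told apart here.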
